A study of Homo sapiens with 30 samples.

How the data were processed

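RNA of 30 libraries from 10 groups of 3 was measured by stranded mRNA sequencing of paired 75 nt reads on a NextSeq instrument, per the labels' protocols. Cells grew in RPMI with 10% dialyzed serum and 2 mM glutamine. Isolation samples were lysed in TRIzol and cleaned with a column kit and optional DNase, and co-culture samples were sorted on a Moflo Astrios and extracted with another column kit, per the labels' protocols. Alignment and quantification used STAR 2.6.1d and Salmon 1.4.0 with GRCh38 (hg38), per the submitters' processing notes. The tool that scaled the values, the annotation, the trimming and any filter are not stated. The deposited values are length-scaled estimated counts per gene, not normalized for depth, in 2 tables of 26475 genes each that were made separately. None of the table columns lacked a sample, so all libraries were mapped by their labels.

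The estimated counts were rounded and tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM normalization, the filterByExpr gene filter, a robust quasi-likelihood fit over all groups of a table and BH adjustment at 0.05. This kept 14570 genes of the first table and 14638 of the second. CPM values are TMM-normalized. Log2 fold changes come from the fit, and standard errors are the log2 fold change over the root of the fit's F statistic. Principal components and list tests used log2 CPM with a prior count of 2. Genes with no more than 3 counts in a group are given as a ratio of summed counts with a 95% interval, or as a least fold at a floor of 3 counts over the group. Reads were copied by PCR without molecular tags, so these intervals cover counting error alone. TMM factors ran from 0.926 to 1.07 in the first table and from 0.946 to 1.04 in the second. The biological coefficient of variation was 10.4% in each table. Between replicates of a group the chi-square per gene ran from 5.20 to 74.7, highest between Pop replicate 1 and the other Pop libraries (54.5 and 74.7).

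Comparisons were made within a table only. They were co-culture against isolation in each lineage, the response shared by 3 lineages (called in each, the same direction), the interaction of lineage and co-culture (F test and pairs), lineage differences in each condition, each of lineages 03, 10 and 13 against Pop, and 03, 10 and 13 against each other. Lineage distance is the root mean square log2 difference over genes less the part due to replicate error, with a jackknife standard error. Lineage genes were at least 8-fold (log2 of 3) above both other isolated lineages, called, and at least 5 CPM. Named genes followed a rule set before the data were examined: the 8 largest rises and 8 largest falls of each contrast at 5 CPM or more without overlap of replicates, the 10 shared rises and falls with the largest smallest change, the 10 smallest p of each F test and up to 4 members with the smallest p of each list described. The comparisons, the alternatives and 31 gene lists were also set before the data were examined. Of 676 list symbols 663 were found, 18 through an older symbol. The list of genes encoded in mitochondrial DNA had no gene in the tables, so 30 lists were tested with camera at the preset correlation of 0.01 and with an estimated correlation, and their members were counted. Results of some genes and of 1 list are not reported. Coordinates are GRCh38 from GENCODE. Window medians used 190 windows of 50 neighboring protein-coding genes, and they were chosen after the first results were seen.

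Whether replicate numbers pair the samples was checked by correlating the deviations of same-numbered libraries from their group means. Only the co-culture groups of 22 and 45 had all 3 correlations above 0.1 (0.36, 0.25 and 0.17), so the numbers may pair these 2 groups, which the labels do not state. The blocked fit called 3703 genes between them against 3669. It gives all groups a common replicate effect, so it does not model a pairing of these 2 alone. Alternatives were DESeq2 1.42.0, RLE normalization, no filter, a stricter filter, a replicate block, fits of the compared groups alone, thinning to the smallest library, leaving out each library, glmTreat at 1.5-fold and a higher threshold for lineage genes. Alternatives without lineage 35 libraries and the shared response outside the range of isolated lineages were added after seeing the data. Chance was tested with all 10 splits of 3 against 3 libraries or with 100 draws of shuffled labels: over the 9 libraries compared for lineage differences, within each lineage for the shared response and over all 18 libraries for the interaction. The last do not keep the lineage differences, so they are no test of the interaction. The shuffle within lineages replaced one over all 18 libraries after the results were seen.

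The calculation was tested on simulated counts with known changes at the depth of these libraries. Each gene had the same spread in all groups of a table, so the false calls below do not cover groups of unlike spread. With 14303 genes, changes of 1.5, 2 and 4-fold were found in 69.9, 86.3 and 96.9% of cases for lineage 22, 69.2, 88.7 and 96.9% for 35 and 71.6, 91.0 and 96.9% for 45, with 4.34, 5.38 and 6.04% false calls. Interaction changes were found in 52.8, 80.4 and 91.9%, shared changes in 61.2, 82.1 and 90.9%, and changes of lineage 03 against Pop in 59.7, 79.7 and 93.8% (14413 genes). The distance estimate gave 0.0951 where the truth was 0 and 0.224 where it was 0.156. A list raised 1.5-fold gave adjusted p = 1.0e-52 at the preset and 4.4e-08 at the estimated correlation, with 0 other lists called.

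Paralogs and overlapping genes (SPANX, TBC1D3, GOLGA8, SULT1A, EIF3C and HLA families, LTB4R and LTB4R2, readthrough names such as TRIM6-TRIM34) are uncertain because reads can be shared. Of all genes, 30 were above 2 CPM in every library of the second table while under 0.5 CPM in every library of the first table. Of the 25 found in the annotation 68% overlap a coding gene on the other strand, against 31.7% of random expressed genes, so antisense genes of the second table are not interpreted. The second table also holds 28 names turned into dates and 4 repeated names, which were kept in the counts of genes and not named.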

Results

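Bulk RNA sequencing measured gene expression in lineages derived from MDA-MB-231, a human breast cancer cell line. The series title places the libraries in work on cooperation between clones through exchanged soluble metabolites. The 30 libraries form 10 groups of 3. A first table of 18 libraries holds lineages 22, 35 and 45, each grown alone for about 24 h in RPMI medium (isolation) and each recovered by FACS after 15 days in a co-culture with 6 members that was passaged through a bottleneck every 3 days. A second table of 12 libraries holds lineages 03, 10 and 13 and a group named Pop, all in isolation. The sources used here do not say what Pop is. Libraries were made from 500 ng RNA with a stranded mRNA kit. The summed counts ran from 29.8 to 38.8 M in the first table and from 28.1 to 35.4 M in the second. The sources do not state that the 3 libraries of a group came from separate cultures, so all p-values measure the spread between these samples. Co-culture libraries also differ from isolation libraries in culture time, sorting and RNA kit, so the co-culture comparisons below measure all of these together. Values after CPM are means ± SD and values after log2 fold changes are ± SE, with n = 3 in each group.

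Lineage 35 in isolation stood far from every other group of the first table. On the first principal component, which held 41.9% of the variance, its libraries lay at 103 to 105 and all others between -39.7 and 5.54. The second component (25.1%) separated lineage 22 in isolation, at 68.2 to 73.6, from lineage 45 in isolation, at 23.1 to 27.4. The co-culture libraries of the 3 lineages lay at -39.7 to -25.5 on the first component and at -46.0 to -2.82 on the second. The biological coefficient of variation within groups was 10.4% in the first table (edgeR).

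**Figure D1:**
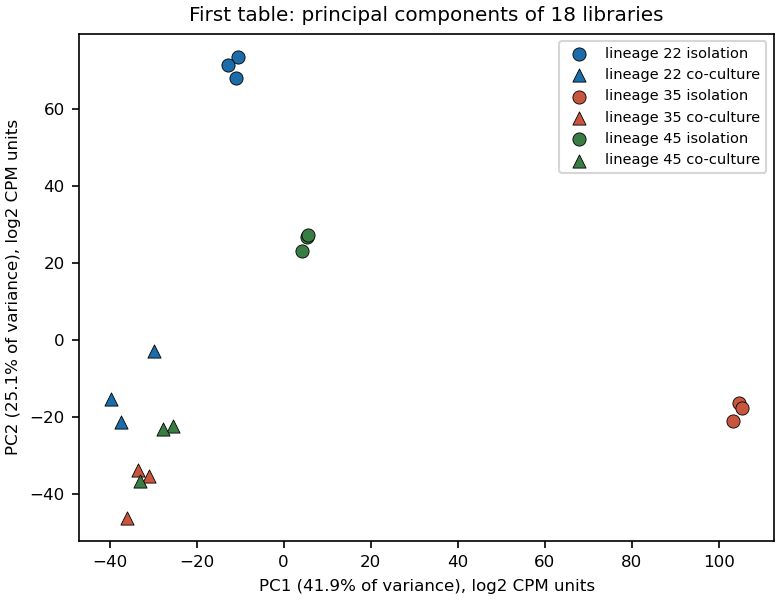
Principal components of the 18 libraries of the first table. Each point is one library, colored by lineage, with isolation and co-culture marked by shape. The percentage of variance is given on each axis.

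Libraries labelled lineage 22 from co-culture held more RNA of cholesterol synthesis genes and less of interferon-stimulated, antigen presentation and cytokine genes than those of the same label in isolation. Whole chromosomes also shifted in this contrast (values below), and whether both groups hold the same cells was not tested. The cholesterol exporters ABCA1 (chromosome 9, 104781002 to 104928237) and ABCG1 (chromosome 21, 42199689 to 42297244), which are driven by sterol-activated receptors, fell 38.9-fold (log2 -5.28 ± 0.37) and 27.6-fold (log2 -4.78 ± 0.32). The secreted peptide TFF1 (chromosome 21, 42362282 to 42366594) fell 24.2-fold (log2 -4.60 ± 0.39), the antiviral gene RSAD2 (chromosome 2, 6865806 to 6898239) 19.2-fold (log2 -4.27 ± 0.21) and the cadherin CDH11 (chromosome 16, 64943753 to 65126112) 16.3-fold (log2 -4.02 ± 0.13). The organic anion transporter SLCO4C1 (chromosome 5, 102233986 to 102296549) rose 18.7-fold (log2 4.23 ± 0.33), from 0.444 ± 0.126 CPM to 8.39 ± 2.58 CPM. Of 14570 genes tested, 3928 were higher and 4368 lower (edgeR, BH-adjusted p < 0.05). Of these, 343 and 1658 changed at least 2-fold, or 169 and 786 under a stricter filter that kept genes with at least 5 CPM in at least 3 libraries. Among interferon-stimulated genes 27 of 32 were lower (27 when adjusted over the list alone) and none higher. DDX60 (4.55-fold), SAMD9L (4.82-fold) and SAMD9 (4.44-fold) were among them. Of 22 NF-kappaB targets and cytokines 18 were lower and 1 higher (the same over the list alone), with PTGS2 falling 9.66-fold, CCL5 8.96-fold and TNFAIP3 3.56-fold. The mesenchymal and matrix list had 15 lower and 3 higher genes of 29 (16 and 3 over the list alone). Of markers of other cell types 2 of 5 fibroblast and 3 of 6 leukocyte ones were lower and none higher, and 3 of 6 endothelial and erythroid ones were lower and 1 higher (the same over each list alone). COL6A3 (chromosome 2, 237324003 to 237414375) fell 6.78-fold (log2 -2.76 ± 0.24) and TGFBI 4.16-fold. S phase genes moved the other way, 18 of 24 higher and 1 lower (18 and 1 over the list alone), with TYMS up 1.69-fold, MCM5 1.64-fold and MCM6 1.57-fold. With 3 against 3 libraries only 10 splits exist, too few for a share below 0.05. The real split, fitted with the compared groups alone, called 3999 higher and 4107 lower genes and no other split called any.

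Lineage 35 cells from co-culture showed the largest change of the 3 lineages by the number of genes called. The X-linked gene FAM133A (chromosome X, 93674013 to 93712274) rose to 10.9 ± 0.873 CPM (ratio 540.3, 95% counting interval 149 to 4467) and SLITRK5 (chromosome 13, 87672615 to 87696272) to 7.81 ± 0.432 CPM (ratio 387, 95% counting interval 107 to 3201). FAM133A is also among the genes that mark lineage 22 in isolation (values below). The coagulation factor F13A1 (chromosome 6, 6144085 to 6321013) rose 134-fold (log2 7.06 ± 0.30), the serine synthesis enzyme PHGDH (chromosome 1, 119648411 to 119744226) 119.8-fold (log2 6.90 ± 0.28), the transcription factor SOX4 (chromosome 6, 21592768 to 21598619) 102-fold (log2 6.67 ± 0.40) and the epithelial gene AGR2 (chromosome 7, 16791811 to 16833433) 86.4-fold (log2 6.43 ± 0.36). The matrix gene THBS2 (chromosome 6, 169215780 to 169254044) fell from 71.8 ± 7.05 CPM (ratio 3706, 95% counting interval 1025 to 30604). RNF144A (chromosome 2, 6917392 to 7068286) fell 129-fold (log2 -7.01 ± 0.58), the hyaluronan-degrading CEMIP (chromosome 15, 80779343 to 80951776) 46.8-fold (log2 -5.55 ± 0.25) and TP53I11 (chromosome 11, 44885903 to 44951306) 38.3-fold (log2 -5.26 ± 0.26). In total 4760 genes were higher and 4789 lower (edgeR, BH-adjusted p < 0.05), 1673 and 1796 of them at least 2-fold, or 878 and 975 under the stricter filter. The genes that mark lineage 35 in isolation were nearly absent from its co-culture libraries (values below), so this contrast compares libraries labelled 35 and may not compare the same cells. Of 19 epithelial junction and keratin genes 16 were higher and 2 lower (the same over the list alone), with KRT81 up 25.7-fold, CD24 10.2-fold and OCLN 4.02-fold. Of 29 ATF4 targets 24 were higher and 2 lower (the same over the list alone), including CEBPB (3.08-fold), AARS (2.18-fold) and STC2 (4.74-fold). Immediate early genes were higher in 21 of 28 cases and lower in 2 (the same over the list alone), with DUSP1 up 14.1-fold and RHOB 8.06-fold. The cytokine gene IL11 and the prostaglandin synthase PTGS2 rose 19.6-fold and 18.3-fold, and 8 NF-kappaB targets of 22 were higher and 2 lower (the same over the list alone). Interferon-stimulated genes split into 13 higher and 13 lower of 32 (13 and 14 over the list alone). MX1 fell 3.51-fold while OASL rose 2.63-fold. Genes used as markers of other cell types moved with this group: 5 of 6 leukocyte markers were higher and 1 lower, and 3 of 6 endothelial and erythroid markers were higher and none lower, while 3 of 5 fibroblast markers were lower and none higher (the same over each list alone). PTPRC rose 17.4-fold, LAPTM5 3.70-fold, PECAM1 20.1-fold and ESAM 18.8-fold. Only 10 splits exist, too few for a share below 0.05. The real split called 4624 higher and 4723 lower genes and no other split called any.

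Lineage 45 cells from co-culture changed least, again with more RNA of cholesterol synthesis genes and less of interferon and antigen presentation genes. Chromosome 7 shifted as a whole (values below), and whether both groups hold the same cells was not tested. The inflammasome gene NLRP2 (chromosome 19, 54953130 to 55001142) rose to 6.07 ± 2.25 CPM (ratio 227, 95% counting interval 77.5 to 1106). EMB (chromosome 5, 50396192 to 50443248) rose 185-fold (log2 7.53 ± 0.31), FRMD3 (chromosome 9, 83242990 to 83538546) 102-fold (log2 6.67 ± 0.53), PTGFRN (chromosome 1, 116910057 to 116990358) 52.7-fold (log2 5.72 ± 0.30) and the lipoprotein receptor LSR (chromosome 19, 35248330 to 35267964) 15.2-fold (log2 3.93 ± 0.15). NLRP2, EMB and FRMD3 are also among the genes that mark lineage 22 in isolation (values below). PI16 (chromosome 6, 36948263 to 36964837) fell 12.1-fold (log2 -3.60 ± 0.47), SCG5 (chromosome 15, 32641676 to 32697098) 8.83-fold (log2 -3.14 ± 0.23) and the steroid-metabolizing AKR1C1 (chromosome 10, 4963253 to 4983283) 7.35-fold (log2 -2.88 ± 0.34). In total 2711 genes were higher and 3375 lower (edgeR, BH-adjusted p < 0.05), 434 and 936 of them at least 2-fold, or 170 and 442 under the stricter filter. Interferon-stimulated genes were lower in 27 of 32 cases (28 over the list alone) and higher in none, with SAMD9L falling 7.68-fold (log2 -2.94 ± 0.12), SAMD9 5.44-fold, OAS2 3.32-fold and IFIT2 3.24-fold. Of 22 NF-kappaB targets 13 were lower and 1 higher (14 and 1 over the list alone). PTGS2 fell 4.16-fold and IL6 2.78-fold, while IL11 rose 3.46-fold. Immediate early genes were higher in 15 of 28 cases and lower in 3 (the same over the list alone), the higher ones including DUSP1 (3.97-fold) and BTG2 (2.86-fold). The matrix list had 12 lower and 3 higher genes of 29 (13 and 3 over the list alone). Of markers of other cell types 3 of 5 fibroblast ones were lower and 1 higher, and 2 of 6 leukocyte and 1 of 6 endothelial and erythroid ones were lower and none higher (the same over each list alone). Only 10 splits exist, too few for a share below 0.05. The real split called 2321 higher and 2874 lower genes and no other split called any.

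Cells of all 3 lineages held more RNA for making sterols and fatty acids, and less RNA for presenting peptides on HLA class I and II, when they came from co-culture. These sterol genes are the known targets of the transcription factor SREBP2, which is active when cell cholesterol is low. INSIG1 (chromosome 7, 155297776 to 155310235) rose 7.42-fold, 6.58-fold and 5.40-fold in lineages 22, 35 and 45 (log2 2.89 ± 0.25, 2.72 ± 0.25 and 2.43 ± 0.25), HMGCS1 (chromosome 5, 43289395 to 43313512) 6.64-fold, 4.31-fold and 6.86-fold, and the desaturase SCD (chromosome 10, 100347124 to 100364834) 6.41-fold, 6.44-fold and 5.12-fold. The exporter ABCA1 fell 38.9-fold, 12.2-fold and 11.9-fold. Of 25 genes of cholesterol synthesis and uptake 25, 23 and 24 were higher (25, 23 and 25 over the list alone), 23 of them in all 3 lineages. The median log2 changes of this list were 1.97, 1.75 and 1.71. In lineage 45 the list test gave adjusted p = 8.8e-25 at the preset correlation and adjusted p = 0.0784 with an estimated correlation (camera, BH-adjusted). Lineages 22 and 35 gave adjusted p = 9.3e-18 and 3.9e-09 at the preset correlation and adjusted p = 0.154 and 0.307 with an estimated correlation. Of 18 fatty acid genes 15, 15 and 14 were higher and 1, 1 and 0 lower (the same over the list alone), 12 of them higher in all 3, including FASN (5.52-fold, 2.69-fold and 2.89-fold) and FADS2 (6.05-fold, 4.95-fold and 3.84-fold). Of 19 antigen presentation genes 17 were lower in all 3 lineages and 18 in each (the same over the list alone). The list test for it gave adjusted p = 5.8e-10, 6.1e-08 and 7.6e-11 at the preset correlation and adjusted p = 0.154, 0.307 and 0.0784 with an estimated correlation. HLA-B fell 4.85-fold, 11.5-fold and 2.13-fold. In the same libraries the nuclear RNA MALAT1 changed by log2 -3.28 ± 0.45, -3.40 ± 0.47 and -2.47 ± 0.44 in lineages 22, 35 and 45. HLA genes are alike and vary between people, so reads may be shared among them. Ribosomal protein genes were higher in 36, 28 and 37 of 37 cases and lower in 0, 4 and 0 (1 more lower in lineage 22 over the list alone), by small amounts such as 1.96-fold for RPS2 in lineage 22. Respiratory chain genes encoded in the nucleus were higher in 31, 19 and 30 of 37 cases (32, 19 and 32 over the list alone) and lower in 2, 5 and 0 (the same over the list alone). FOS (6.87-fold, 16.8-fold and 6.39-fold), the metastasis suppressor KISS1 (5.73-fold, 11.9-fold and 10.3-fold) and the aldolase ALDOC (4.34-fold, 9.11-fold and 5.38-fold) rose in each lineage. In all 3 lineages 1132 genes were higher and 1543 lower (edgeR, BH-adjusted p < 0.05 in each). If the calls were independent 239 and 333 would be. The level in all 3 co-culture groups lay outside the range of the 3 isolated lineages for 590 of the higher and 957 of the lower genes. In 100 draws with isolation and co-culture labels shuffled within each lineage, the real labels included, no other draw called a shared gene. With lineages 22 and 45 shuffled alike, since their replicate numbers may pair them, other draws called at most 331. Of 30 lists 12 rose and 5 fell in lineage 22, 9 and 1 in lineage 35, and 13 and 3 in lineage 45 at the preset correlation, and none of these calls held with an estimated correlation. Other splits of the libraries called 15, 14 and 18 lists at most, against 16, 9 and 16 for the real split in the same fits of the compared groups alone, so these list p-values are not read as evidence here.

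**Figure D2:**
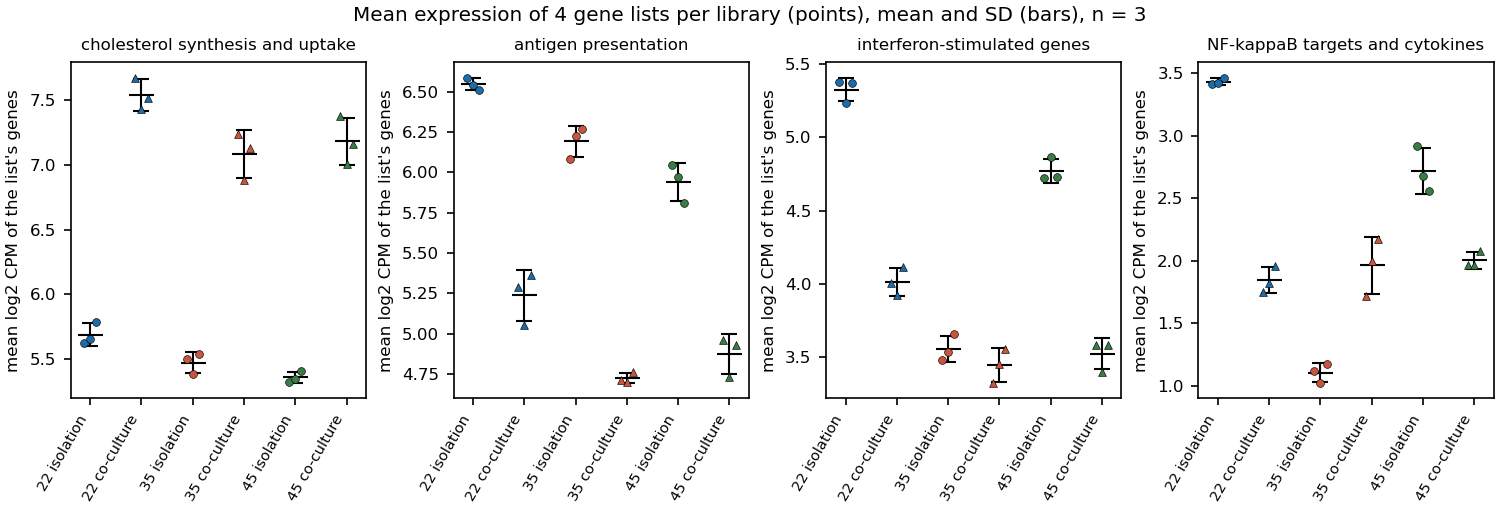
Mean log2 CPM over the genes of 4 lists (cholesterol synthesis and uptake, antigen presentation, interferon-stimulated genes, NF-kappaB targets and cytokines) in each library of lineages 22, 35 and 45. Points are libraries and bars give mean and SD, n = 3.

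The change from isolation to co-culture differed between the lineage labels in many genes, and most of these genes set label 35 apart. The groups labelled 35 may not hold the same cells, so these values may not measure a response of lineage 35. Its co-culture libraries correlated less with isolated 35 (mean r = 0.924) than with isolated 45 (0.964) or 22 (0.950). Among the isolation groups, co-culture libraries of 22 and 45 correlated most with their own lineage (0.962 and 0.970). The liver and gut regulator FOXA2 (chromosome 20, 22581005 to 22585455) rose 55.6-fold in lineage 35 and 1.70-fold in lineage 22. The amine oxidase MAOA (chromosome X, 43654907 to 43746824) rose 33.9-fold (log2 5.08 ± 0.11) in lineage 35 and fell 2.24-fold (log2 -1.16 ± 0.07) in lineage 22. Netrin NTN4 (chromosome 12, 95657807 to 95791152) rose 14.3-fold (log2 3.84 ± 0.12) in lineage 35 and fell 2.06-fold and 1.55-fold in lineages 22 and 45. The mesenchymal cadherin CDH11 rose 5.53-fold (log2 2.47 ± 0.14) in lineage 35 and fell 16.3-fold in lineage 22 and 2.54-fold in lineage 45. The flippase ATP10A (chromosome 15, 25677273 to 25865172) rose 53.6-fold in lineage 35, with log2 changes of 0.13 ± 0.10 and -0.13 ± 0.10 in lineages 22 and 45 that were not called. The differences in response between lineages 35 and 45 were 5.87 ± 0.19 for ATP10A and 5.17 ± 0.13 for MAOA in log2 units (BH-adjusted p = 2.3e-15 and 1.3e-16). An interaction test called 8041 genes (edgeR, F test over 3 lineages, BH-adjusted p < 0.05). By pair 7233 genes differed between lineages 22 and 35, 2524 between 22 and 45 and 6158 between 35 and 45. Without the lineage 35 co-culture libraries only the pair of 22 and 45 remained, with 2391 genes called against 2524. Log2 changes correlated across genes with r = 0.57 between lineages 22 and 45, 0.41 between 35 and 45 and 0.27 between 22 and 35. Of genes called in lineages 22 and 45, 4261 moved the same way and 262 opposite ways, against 4133 and 1696 for lineages 22 and 35. Among 100 draws with labels shuffled over all 18 libraries the highest other count was 4444, and for the pair of 22 and 45 3 draws, the real one included, gave at least the real 2524, the highest being 3264. Shuffling over all libraries breaks the lineage differences too, so these draws stand for libraries without any groups and do not test the interaction.

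The 3 lineages were much less different from each other in co-culture than in isolation. In isolation, lineage 35 lacked genes that lineages 22 and 45 expressed. MAOA was 79.8-fold (log2 6.32 ± 0.11) higher in lineage 22 than in 35, AFF3 (chromosome 2, 99545419 to 100142739) 423-fold (log2 8.73 ± 0.21), NTN4 40.0-fold (log2 5.32 ± 0.12), the signaling lipase PLCG2 (chromosome 16, 81739097 to 81962693) 27.4-fold (log2 4.78 ± 0.11) and the endothelial adhesion gene ESAM (chromosome 11, 124752583 to 124762290) 13.1-fold (log2 3.71 ± 0.09). The cancer-testis gene SPANXB1, whose copies on the X chromosome are nearly identical, was 123-fold higher in lineage 22. In co-culture the clearest differences marked lineage 22. The proteoglycan CSPG4 (chromosome 15, 75674322 to 75712848) was 6.78-fold (log2 2.76 ± 0.13) higher in lineage 22 than in 35 and 3.00-fold (log2 1.59 ± 0.12) higher than in 45. The TGF-beta co-receptor ENG (chromosome 9, 127815012 to 127854756) was 22.0-fold (log2 4.46 ± 0.29) and 19.4-fold (log2 4.28 ± 0.28) higher, COBL (chromosome 7, 51016212 to 51316818) 18.2-fold (log2 4.19 ± 0.26) and 8.18-fold (log2 3.03 ± 0.23) and VIPR1 (chromosome 3, 42489299 to 42537573) 4.03-fold and 8.57-fold. PTGFRN was 10.6-fold (log2 -3.41 ± 0.24) lower in lineage 35 than in 45. In isolation 10364 genes differed among the 3 lineages and in co-culture 5368 (edgeR, F test, BH-adjusted p < 0.05). By pair the counts were 9262 (22 and 35), 5598 (22 and 45) and 7553 (35 and 45) in isolation and 4530, 3669 and 1851 in co-culture. The 3669 between 22 and 45 became 1805 when only the groups compared were in the fit. The typical size of the log2 difference, after removal of the replicate error, fell from 1.47 (jackknife SE 0.0435) to 0.60 (0.0465) between 22 and 35, from 0.83 (0.0292) to 0.51 (0.0386) between 22 and 45 and from 1.23 (0.0232) to 0.45 (0.0293) between 35 and 45. Under the stricter filter these sizes were 1.08, 0.62 and 0.93 in isolation and 0.43, 0.39 and 0.33 in co-culture. The same estimate gave 0 for the interaction of each pair, where 7233, 2524 and 6158 genes were called. The removal of replicate error can thus take away too much. In simulated data it took away too little (0.0951 where the truth was 0 and 0.224 where it was 0.156). The sizes can therefore be off in either direction, which the jackknife errors do not cover. Of 2309 genes at least 2-fold apart between 35 and 45 in isolation, 52.2% kept the same sign in co-culture and the median size went from 1.84 to 0.35. For 22 and 45 the 1167 such genes kept the sign in 82.1% of cases and the median size went from 1.61 to 0.78. For 22 and 35 the 3023 genes kept it in 60.7%, from 1.76 to 0.44. All these genes were chosen by their size in isolation, so part of the fall follows from the choice. The reverse choice was not made. Only 10 splits exist for each pair. The real split called 3608, 1805 and 1355 genes in co-culture (22 and 35, 22 and 45, 35 and 45) and 9766, 7134 and 7616 in isolation, and the highest other split called 3. Over all 3 lineages the real labels called 11100 genes in isolation and 3893 in co-culture, and the highest of 100 draws 5620 and 556.

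Genes found in a single isolated lineage trace how far each lineage kept its own profile. The 9 genes at least 8-fold higher in lineage 35 than in both other isolated lineages summed to 216 ± 8.11 CPM in isolation and to 6.50 ± 0.703 CPM in its co-culture libraries, or 3.01%. The co-culture libraries of lineages 22 and 45 held 2.95 and 4.65%. The 30 genes of lineage 22 went from 476 to 331 CPM, or 69.6%, and reached 24.3% in the co-culture libraries of 35 and 16.7% in those of 45. In isolation lineages 35 and 45 held 1.71 and 3.49% of that sum. The medians over the 30 genes were lower than these sums, at 49.4% in the co-culture libraries of 22, 13.0% in those of 35 and 10.4% in those of 45. In the co-culture libraries of 35 the genes NLRP2, EMB and FAM133A held 26.4, 12.9 and 10.9 CPM of the summed 115.5 CPM. The means of EMB and FAM133A there were above those in the co-culture libraries of 22 (8.35 and 3.49 CPM). Carry-over of cells like those sorted as 22 cannot alone give these values. Most of the 30 genes were lower there than in the co-culture libraries of 22, NLRP2 (38.6 CPM in 22) included. For these, lineage 22 cells carried over at the sort and a change of expression in 35 and 45 were not told apart. Lineage 45 had 3 such genes, COX7B2, CST1 and SEMA3E (named after their values were seen), at 57.7% of their sum in its own co-culture libraries, 43.4% in those of 35 and 11.1% in those of 22. These sums rest on single genes. In lineage 45 CST1 fell from 40.3 to 8.47 CPM while COX7B2 went from 6.55 to 9.63 CPM and SEMA3E from 7.98 to 13.5 CPM, and SEMA3E made up 22.1 of 23.8 CPM in the co-culture libraries of 35. Chromosome-wide differences changed in both directions. Between lineages 35 and 45 in isolation the median log2 difference over the genes of a chromosome was 0.61 on chromosome 18, 0.50 on 15, 0.45 on 6, -0.34 on 12 and -0.25 on 14. In co-culture the same medians were 0.03, -0.03, -0.02, 0.01 and 0.06. The median went from -0.06 in isolation to 0.20 in co-culture on chromosome 7, from -0.01 to 0.13 on 4, from -0.00 to 0.11 on 19 and from -0.19 to 0.33 on X. Between 22 and 45 the median on chromosome 7 was -0.51 in isolation and -0.14 in co-culture. Within lineage 22, window medians of co-culture against isolation were -0.83 to -0.70 on X and -0.44 to -0.21 on chromosome 4. Within lineage 45 they were -0.39 to -0.13 on chromosome 7. Copy number itself was not measured. In simulated data, differences kept in co-culture gave a correlation of 0.996 between conditions over windows of 50 genes. Differences placed in isolation alone gave 0.140. All genes of a window were moved alike there and no other change was simulated. The real correlations were 0.40 (22 and 45), -0.159 (35 and 45) and -0.0290 (22 and 35), each within the 95% range of shuffled genes. The simulated values thus do not show that the correlation separates these cases in the real data.

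**Figure D3:**
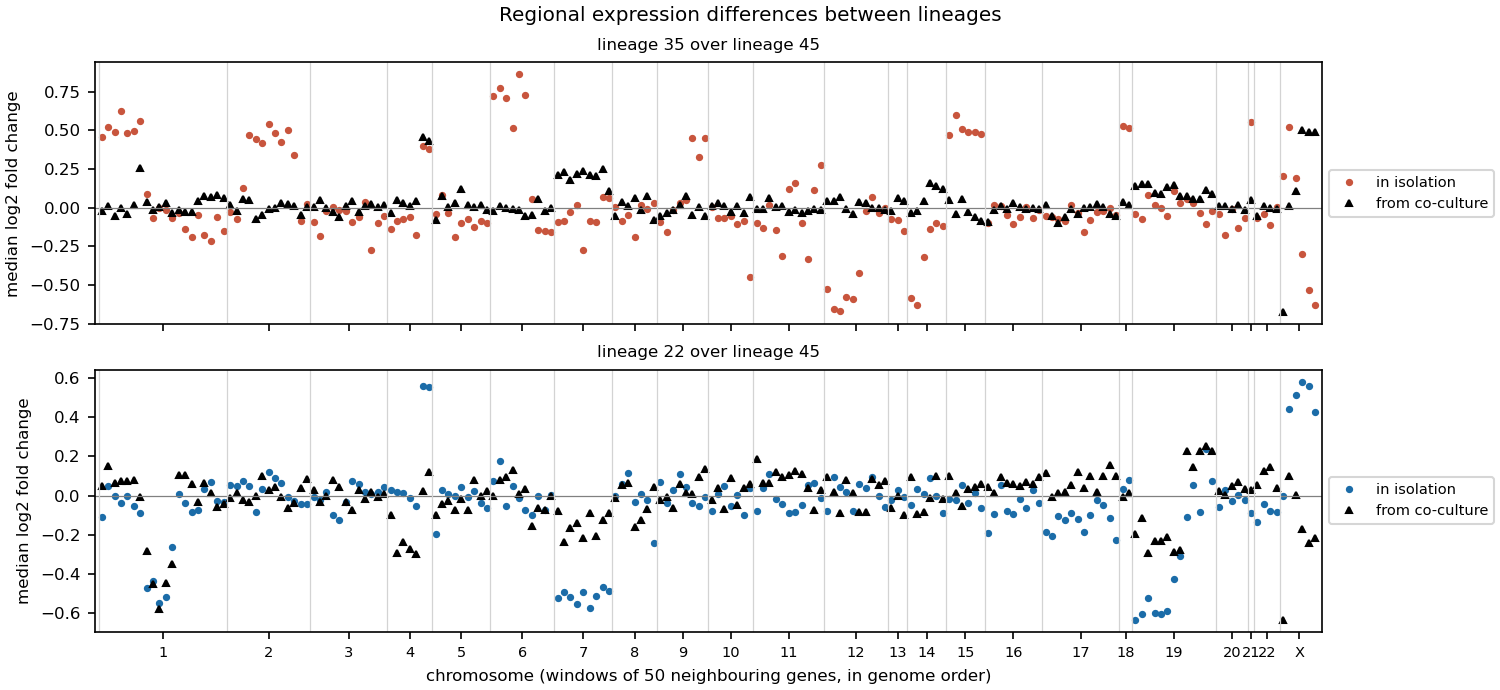
Median log2 difference between lineages 35 and 45 (top) and between 22 and 45 (bottom) in windows of 50 neighboring genes along the genome, in isolation and from co-culture.

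Lineage 03 held more RNA of antigen presentation and NF-kappaB genes than Pop, and less of epithelial and glycolytic genes. The secreted ribonuclease RNASE1 (chromosome 14, 20801228 to 20803278) was present at 13.4 ± 1.60 CPM (ratio 1347, 95% counting interval 241 to 53260.0). SSPO (chromosome 7, 149776042 to 149833979) was 97.7-fold (log2 6.61 ± 0.18) higher, the adhesion molecule VCAM1 (chromosome 1, 100719742 to 100739045) 29.9-fold (log2 4.90 ± 0.25) and the gelatinase MMP9 (chromosome 20, 46008908 to 46016561) 25.3-fold (log2 4.66 ± 0.32). No count of the flippase ATP10A or the protease ADAMTS1 (chromosome 21, 26835747 to 26845409) was found in lineage 03, so they were at least 862-fold and at least 627-fold lower. The epithelial gene AGR2 was at least 490.4-fold lower. In total 3397 genes were higher and 3727 lower than in Pop of 14638 tested (edgeR, BH-adjusted p < 0.05), 676 and 1067 of them at least 2-fold, or 392 and 372 under the stricter filter. Antigen presentation genes were higher in 17 of 19 cases and lower in none (19 higher over the list alone), with HLA-F up 5.33-fold, HLA-DRB1 6.88-fold and CD74 5.28-fold. NF-kappaB targets were higher in 18 of 21 and lower in 2 (the same over the list alone), with ICAM1 up 5.97-fold and BIRC3 5.52-fold, while IL11 was 23.2-fold lower. Glycolytic genes were lower in 17 of 23 cases and higher in 3 (the same over the list alone), the lower ones including HK2 (2.80-fold) and GAPDH (2.19-fold). Epithelial genes were lower in 10 of 17 and higher in 2 (10 and 3 over the list alone), with KRT81 32.2-fold and CD24 19.3-fold lower. Of markers of other cell types 3 of 3 endothelial and erythroid ones were lower (median log2 -2.50), 1 of 4 leukocyte ones was higher, and 2 fibroblast ones were higher and 2 lower of 6 (the same over each list alone). Only 10 splits exist. The real split called 2797 higher and 2904 lower genes and no other split called any.

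Lineage 10 held less RNA of many epithelial, matrix and interferon-stimulated genes than Pop. The cadherin CDH11 and the apical membrane gene MAL2 (chromosome 8, 119165034 to 119245673) had no count in lineage 10 and were at least 3125-fold and at least 936-fold lower than in Pop. AGR2, the mucin MUC5AC (chromosome 11, 1157953 to 1201138) and the tetraspanin TSPAN8 (chromosome 12, 71125085 to 71441898) were at least 518-fold, at least 411-fold and at least 256-fold lower. The scramblase family gene ANO5 (chromosome 11, 21799934 to 22283357) was 41.8-fold (log2 5.39 ± 0.26) higher, RIMS2 (chromosome 8, 103500748 to 104256094) 5.49-fold (log2 2.46 ± 0.18) and the phosphodiesterase PDE9A (chromosome 21, 42653636 to 42775509) 5.14-fold (log2 2.36 ± 0.32). In total 2749 genes were higher and 3438 lower (edgeR, BH-adjusted p < 0.05), 254 and 1171 of them at least 2-fold, or 118 and 465 under the stricter filter. Matrix genes were lower in 19 of 29 cases and higher in 6 (the same over the list alone). MMP1 was 30.1-fold lower, TNC 6.33-fold and COL6A2 4.90-fold. Epithelial genes were lower in 12 of 17 and higher in 1 (the same over the list alone), with KRT81 18.1-fold and KRT7 3.87-fold lower. Interferon-stimulated genes were lower in 16 of 32 and higher in 2 (19 and 2 over the list alone), with OAS1 8.09-fold and IFI27 6.39-fold lower. The serine synthesis enzyme PHGDH was nearly absent (0.0103 ± 0.0179 CPM, ratio 706, 95% counting interval 126 to 27926). Cholesterol genes were higher in 11 of 25 and lower in 2 (the same over the list alone), with MSMO1 1.58-fold higher. Other lists had more lower than higher genes: glycolysis had 13 lower and 1 higher of 23, hypoxia-inducible factor targets 11 and 4 of 24, S phase 11 and 0 of 24 and TGF-beta targets 9 and 2 of 19. Hypoxia-inducible factor targets and S phase genes were not called as lists at the preset correlation (camera, BH-adjusted p = 0.171 and 0.0639). Of markers of other cell types 2 of 4 leukocyte, 2 of 3 endothelial and erythroid and 3 of 6 fibroblast ones were lower and none higher (the same over each list alone). Only 10 splits exist. The real split called 2488 higher and 3118 lower genes and no other split called any.

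Lineage 13 also held less RNA of epithelial, matrix, interferon-stimulated and hypoxia-induced genes than Pop. The collagenase MMP1 was 451-fold (log2 -8.82 ± 0.49) lower and the prostaglandin synthase PTGS2 at least 99.8-fold lower. CDH11 was at least 3317-fold lower. The kinase scaffold KIDINS220 (chromosome 2, 8721081 to 8837630) was 7.08-fold (log2 2.82 ± 0.08) higher, the neural adhesion gene NCAM2 (chromosome 21, 20998315 to 21543329) 6.19-fold (log2 2.63 ± 0.20), the endothelial gene THSD1 (chromosome 13, 52377167 to 52416373) 4.69-fold (log2 2.23 ± 0.21) and DMBT1 (chromosome 10, 122560665 to 122643736) 4.25-fold (log2 2.09 ± 0.25). In total 3080 genes were higher and 3538 lower (edgeR, BH-adjusted p < 0.05), 359 and 1299 of them at least 2-fold, or 148 and 552 under the stricter filter. Interferon-stimulated genes were lower in 26 of 32 and higher in 1 (26 and 2 over the list alone), with OASL 4.87-fold and DDX60 3.03-fold lower. Hypoxia-inducible factor targets were lower in 16 of 24 and higher in none (the same over the list alone), with EGLN3 7.04-fold and CA12 3.07-fold lower. Epithelial genes were lower in 13 and higher in 3 of 17 and matrix genes in 20 and 4 of 29 (the same over each list alone), with KRT81 169-fold and COL1A2 6.39-fold lower. The oxidative stress genes NQO1 and OSGIN1 were 2.38-fold and 2.55-fold higher. Markers of other cell types moved with this group: 4 of 4 leukocyte and 3 of 3 endothelial and erythroid ones were lower, and 4 of 6 fibroblast ones were lower and 1 higher (the same over each list alone). Only 10 splits exist. The real split called 2543 higher and 2900 lower genes and no other split called any. The Pop libraries serve in all 3 of these comparisons, so overlap between them is not counted here. Of 30 lists 3 were higher and 7 lower in lineage 03, 1 and 6 in lineage 10 and 1 and 11 in lineage 13 at the preset correlation, and none of these calls held with an estimated correlation. Other splits called 11, 11 and 13 lists at most, against 10, 9 and 11 for the real split in the same fits of the compared groups alone.

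**Figure D4:**
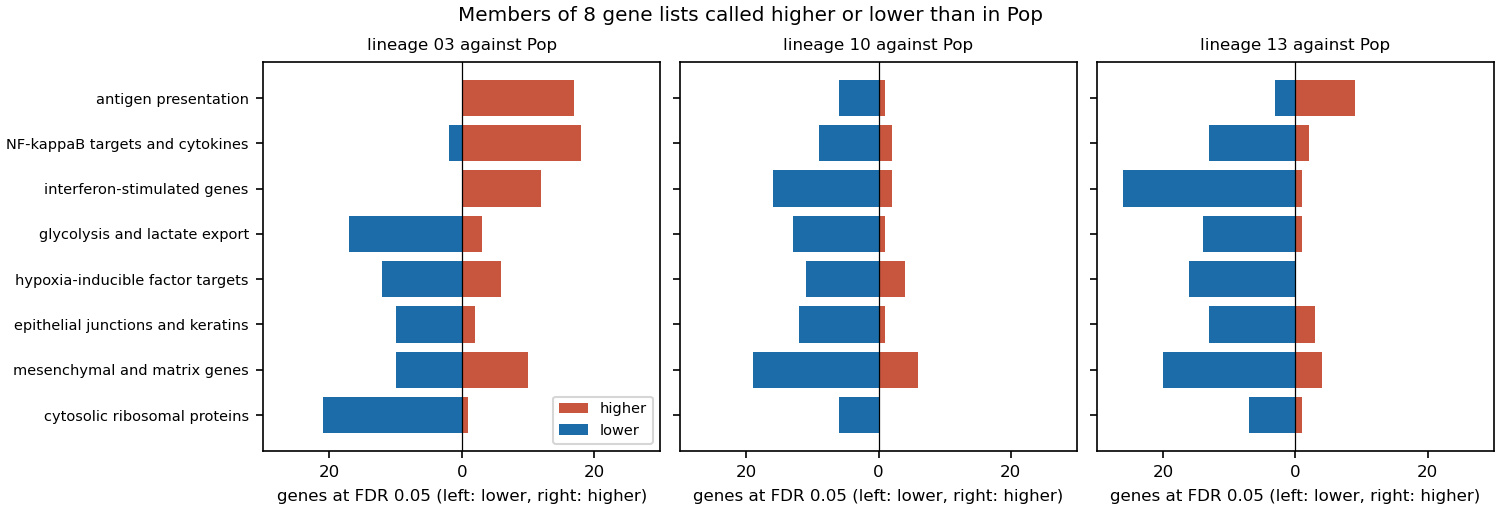
Numbers of genes of 8 lists called lower (left) or higher (right) in lineages 03, 10 and 13 than in Pop, at a BH-adjusted p below 0.05.

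Lineage 03 was also the most distinct of lineages 03, 10 and 13 by the number of genes called. Collagen COL6A2 (chromosome 21, 46098097 to 46132849) was 20.4-fold (log2 4.35 ± 0.09) higher in 03 than in 10 and 18.3-fold (log2 4.20 ± 0.09) higher than in 13. TP53I11 was 121-fold (log2 6.92 ± 0.18) and 198-fold (log2 7.63 ± 0.19) higher, the complement gene C2 (chromosome 6, 31897785 to 31945672) 219-fold (log2 7.78 ± 0.20) and 24.0-fold (log2 4.59 ± 0.15) and the kinase ALPK2 (chromosome 18, 58481247 to 58628957) 73.7-fold (log2 6.20 ± 0.19) and 204-fold (log2 7.67 ± 0.21). KIDINS220 set lineage 13 apart, 5.65-fold (log2 -2.50 ± 0.08) lower in 10 and 7.59-fold (log2 -2.92 ± 0.08) lower in 03. Among the 3 lineages 9693 genes differed (edgeR, F test, BH-adjusted p < 0.05), 7528 between 03 and 10, 7790 between 03 and 13 and 5072 between 10 and 13. In 100 draws of shuffled labels at most 1146 genes were called, against 10314 for the real labels in the same fit. The real split of each pair called 8343 (03 and 10), 7534 (03 and 13) and 6067 (10 and 13) genes and no other split called any.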

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

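The tests of a minority of other cells, of the cholesterol and antigen presentation pattern and of genomic DNA below were chosen only after the result was seen. The results of this paragraph stand here because the same contrast differed between the lineage labels by an interaction test. The groups labelled 35 may not hold the same cells. The 3 patterns after this paragraph are weighed for technical causes. The response to co-culture differed between the 3 lineages in 8041 genes, between 22 and 35 in 7233, between 22 and 45 in 2524 and between 35 and 45 in 6158 (edgeR, BH-adjusted p < 0.05). The smallest adjusted p of the interaction belonged to MAOA (1.65e-17), SPANXB1 (6.01e-17), FOXA2 (1.11e-16), ESAM (3.88e-16), MISP (1.91e-15), ACSS3 (2.25e-15), ATP10A, NTN4 and CDH11 (2.5e-15 each) and TMEM156 (2.66e-15). For MISP the log2 changes were 0.12 ± 0.09, 4.55 ± 0.12 and -0.62 ± 0.09 in lineages 22, 35 and 45, for ACSS3 0.49 ± 0.09, 5.21 ± 0.12 and 0.20 ± 0.08 and for TMEM156 -0.14 ± 0.11, 5.38 ± 0.15 and -0.19 ± 0.11.

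Co-culture libraries of lineage 35 lacked the genes that mark lineage 35 in isolation. Without these libraries only the responses of 22 and 45 can be compared, with 2391 genes called against 2524 in the full fit. That does not show how far these libraries drive the interaction. A minority of other cells in the lineage 35 sort is excluded as the whole cause, because the marking genes, chosen from isolation alone, kept at most a median of 2.94% of their isolation level in any of the 3 libraries, where mostly lineage 35 cells of unchanged expression would keep at least 50%. Cells of another lineage under the label 35 in one of the conditions stay possible: the regional differences between 35 and 45 did not return in co-culture (r = -0.159 over 190 windows, within the -0.168 to 0.129 of shuffled genes, and -0.0290 between 22 and 35), but the control pair 22 and 45 gave 0.40 (95% bootstrap interval 0.22 to 0.57), below the 0.5 foreseen and within the 0.18 to 0.43 of shuffled genes. The correlation does not exclude a change of expression of the same lineage 35 cells, since the same control failed (upper bound -0.00796). Window medians of lineage 35 in co-culture against isolation, read after the results were seen, argue against it where neighboring genes moved together. They were -0.58 to -0.41 on chromosome 15, -0.57 and -0.41 on 18 and 0.54 to 0.81 on 12 up to the window at 56731596. Beyond it they were 0.03 to 0.12, and -0.01 to 0.17 on 16. In isolation the 35 and 45 difference had a window SD of 0.29, against 0.07 with shuffled genes. Such blocks are not particular to label 35. Within lineage 22 the medians were -0.83 to -0.70 on X and -0.44 to -0.21 on chromosome 4. Within lineage 45 they were -0.39 to -0.13 on chromosome 7. The same reading would bear on lineages 22 and 45, where it was not tested. Copy number was not measured, and for other genes the explanation stays open. Genotypes or barcodes in the reads, which are not in these tables, would separate these explanations.

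Cholesterol genes rose and antigen presentation genes fell in every co-culture group. A mixture of the lineages' cells in the sorts is excluded for the cholesterol genes only if it was made of lineages 22, 35 and 45, because 88% of them lay above all 3 isolated lineages in all 3 co-culture groups, where such a mixture would stay within their range. Cells of the other 3 members of the co-culture were not compared and stay open. Handling during dissociation and sorting stays open and was not tested apart: the immediate early list was called as higher in 2 of 3 contrasts at the preset correlation (35 and 45, adjusted p = 0.307 and adjusted p = 0.281 with an estimated correlation), and such list calls are not read as evidence. The biological explanation, 15 days of co-culture, cannot be separated from it, since 0 groups were co-cultured and not sorted or sorted and not co-cultured.

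Replicate 3 of the lineage 22 co-culture had 19134 genes above 0, against 15851 to 17485 in the other libraries of the table. Genomic DNA in the library fits, because 149 olfactory receptor genes had counts, against 6 to 23 elsewhere, or 6.48 times the highest other library. RNA of other cells or tissue stays open, because a fixed set of genes of other tissues summed to 14.5 CPM, of which 13.0 CPM was GFAP, a gene that also reached 10.1 CPM elsewhere, and the 17 genes under 1 CPM in every other library summed to 0.529 CPM. Greater depth stays formally open: after thinning the library kept 1.09 times the genes of the highest other, between the limits foreseen, although its total of 32.1 M counts lay below the median of 35.4 M. No biological explanation was tested for this library.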

How the results depend on the processing

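The alternatives without lineage 35 and the range of isolated lineages were chosen only after the result was seen. No result changed direction under any alternative. Counts of called genes stayed within 1.5 times under DESeq2, RLE, no filter, the replicate block and thinning, and under the fits of the compared groups alone except for 22 against 45 in co-culture (1805 against 3669). The isolation count of the same pair went the other way (7134 against 5598). Between replicates the chi-square per gene was 16.1 to 47.0 (22) and 19.3 to 46.8 (45) in co-culture. In isolation it was 6.09 to 8.82 and 7.72 to 25.9. The main fit uses a spread common to all groups, so its counts between lineages from co-culture may be too high. The cause was not tested. Of 431 values of named genes 428 kept their call under every setting that gave them a value, and the 20 lost calls (6079 kept) belong to SPANXA2, TRIM6-TRIM34 and EIF3CL in lineage 22. The replicate block changed no other call of this size: it gave 3950 genes higher in co-culture for lineage 22 against 3928.

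Under the stricter filter fewer genes were tested, and the counts at least 2-fold higher and lower were 169 and 786 in lineage 22, 878 and 975 in 35, 170 and 442 in 45, 392 and 372 in lineage 03 against Pop, 118 and 465 in 10 and 148 and 552 in 13. Lineage distances under it were 1.08 (22 and 35), 0.62 (22 and 45) and 0.93 (35 and 45) in isolation and 0.43, 0.39 and 0.33 in co-culture, since weakly expressed genes are left out. Without the lineage 35 co-culture libraries 1947 genes were higher in the remaining 2 lineages, 2391 differed in response and 3462 differed between lineages from co-culture. Without all lineage 35 libraries these were 1911, 2303 and 3308, and 5354 genes differed in isolation. Fewer lineages then had to pass or could differ, by construction. For 22 and 45 alone the full fit called 1870 higher genes, 2524 in response, 3669 from co-culture and 5598 in isolation. Outside the range of the isolated lineages the shared counts were 590 and 957. With an estimated correlation 0 of the 72 gene list calls stayed. RLE gave 72 and the replicate block 71 (6 against 7 lists in lineage 10). At log2 of at least 5 the lineage 22 genes reached 66.0, 19.3 and 8.66% of their isolation level in the co-culture libraries of 22, 35 and 45, the lineage 35 genes 0.361, 0.875 and 0.733% and the single lineage 45 gene 5.10, 14.4 and 147%. Fewer genes are summed there.

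Leaving out each library in turn moved the distances to 1.48 to 1.53 (22 and 35), 0.84 to 0.87 (22 and 45) and 1.24 to 1.27 (35 and 45) in isolation and to 0.59 to 0.66, 0.52 to 0.57 and 0.46 to 0.50 in co-culture. The counts of genes stayed within 1.5 times. For lineage 22 they ran from 3478 to 3832 higher and 3867 to 4315 lower, for 35 from 4387 to 4596 and 4446 to 4611, for 45 from 2059 to 2732 and 2755 to 3224, and for the shared response from 908 to 1209 and 1339 to 1578. The interaction ran from 7472 to 8320. Without lineage 22 co-culture replicate 3 the counts were 3702 and 3991 in lineage 22, 1209 and 1514 shared, 8070 for the interaction and 4679 between lineages from co-culture. Without Pop replicate 1 they were 3400 and 3610 (03), 2855 and 3413 (10) and 3066 and 3751 (13). Thinning to the smallest library left the calls of all 431 values of named genes the same.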

Other observations

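Genes of other groups were also called with co-culture, and the tests in this part that concern single genes outside the naming rule were chosen only after the result was seen. Over all 14570 genes 56.9, 65.5 and 41.8% were called in lineages 22, 35 and 45. Counts near these shares do not set a group apart. The lists of TGF-beta targets, NRF2 targets, polyamine genes and endoplasmic reticulum stress were called in no lineage by camera at the preset correlation. Heat shock genes were higher in 12, 9 and 10 and lower in 1, 3 and 0 of 15 cases in lineages 22, 35 and 45 (the same over the list alone), with DNAJB1 up 1.62-fold, 1.59-fold and 1.29-fold. Genes of the tricarboxylic acid cycle were higher in 20, 13 and 15 and lower in 3, 7 and 2 of 28, and IDH1 rose 1.90-fold, 1.98-fold and 2.18-fold. Glycolytic genes were higher in 14, 16 and 12 and lower in 3, 3 and 2 of 23. LDHB rose 1.64-fold, 2.20-fold and 1.35-fold. Purine and pyrimidine genes were higher in 15, 14 and 11 and lower in 4, 4 and 1 of 23. MYC targets were higher in 18, 11 and 12 and lower in 0, 2 and 0 of 24. Glutamine genes were higher in 7, 10 and 9 and lower in 2, 2 and 0 of 16. Serine and one-carbon genes were higher in 9, 8 and 11 and lower in 3, 5 and 2 of 17, while the glycine cleavage gene AMT fell 11.3-fold, 11.8-fold and 10.1-fold. Endoplasmic reticulum stress genes were higher in 0, 10 and 7 and lower in 9, 4 and 0 of 21. DNAJB9 fell 3.16-fold in lineage 22 and XBP1 rose 1.93-fold in 35. ATF4 targets were higher in 8, 24 and 14 and lower in 7, 2 and 1 of 29, and STC2 fell 4.67-fold in lineage 22. NRF2 targets were higher in 11, 5 and 7 and lower in 9, 14 and 9 of 26, and ABCC3 fell 2.09-fold, 3.08-fold and 2.87-fold. Hypoxia-inducible factor targets were higher in 2, 10 and 4 and lower in 14, 8 and 5 of 24. VEGFA fell 3.31-fold in lineage 22 and ANGPTL4 rose 11.9-fold in 35. TGF-beta targets were higher in 5, 7 and 8 and lower in 9, 8 and 6 of 19, and PMEPA1 fell 3.37-fold, 4.34-fold and 3.33-fold. YAP and TAZ targets were higher in 6, 9 and 6 and lower in 4, 2 and 4 of 20. Polyamine genes were higher in 7, 8 and 7 and lower in 5, 5 and 1 of 18. G2 and mitosis genes were higher in 11, 6 and 4 and lower in 1, 8 and 4 of 24. CDC20 rose 1.68-fold in lineage 22 and KIF23 fell 2.09-fold in 35. S phase genes split into 9 higher and 7 lower in 35 and 5 and 4 in 45.

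The 3 nuclear RNAs MALAT1, NEAT1 and KCNQ1OT1 were lower in all co-culture groups. They were chosen after their values were seen. MALAT1 measured 30.9 ± 23.9 against 302 ± 17.1 CPM (co-culture against isolation) in lineage 22 and 26.8 ± 14.1 against 149 ± 3.85 CPM in 45. NEAT1 changed by -3.24 ± 0.64, -3.15 ± 0.64 and -2.16 ± 0.61 and KCNQ1OT1 by -3.13 ± 0.34, -2.09 ± 0.36 and -2.62 ± 0.35. These move with the same libraries as the cholesterol and antigen presentation genes. On the X chromosome the median difference between 22 and 45 was 0.45 in isolation and -0.17 in co-culture.

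Whether chance divides the libraries as well as their labels was tested for each count of genes and lists. For each comparison of 3 against 3 libraries 1 of 10 splits, the real one, gave a count of genes as large. For the lists 1, 5 and 2 of 10 splits gave as many calls in lineages 22, 35 and 45 and 2, 7 and 2 of 10 for lineages 03, 10 and 13 against Pop. For the tests over 3 lineages 1 of 100 draws, the real one, gave a count as large, and 3 of 100 for the difference in response between 22 and 45. A chance division of libraries taken as independent is excluded for the shared response, where labels were shuffled within each lineage. The same holds for the lineage differences over 3 lineages. Shuffled draws hold the real difference inside their groups, which can lower their counts. Separate cultures are not stated, so a difference made by a single culture, sort or extraction per group is not excluded. The draws over all 18 libraries break the lineage differences too, so they do not test the interaction or its pairs. The 10 splits are too few to exclude a chance division elsewhere. Replicate numbers may pair the co-culture groups of 22 and 45. Of the 10 splits of these groups 4 part all 3 pairs, and neither they nor the 6 that part fewer called a gene, the real one (1805 genes) aside. Of the 100 draws over the co-culture libraries 41 part all 3 pairs, with at most 134 genes against 3893, and the 59 that part fewer called at most 556. For the shared response 100 draws with lineages 22 and 45 shuffled alike called at most 331 genes, against 1132 and 1543 for the real labels. These paired draws were chosen after the results were seen.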
